A study of Homo sapiens with 42 samples.

How the data were processed

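Gene expression was measured by RNA sequencing in 42 samples of 5 human B-ALL cell lines, 3 arms per line, with 2 replicates per arm in Reh and 3 in the other lines. RNA was extracted with RNeasy kits and libraries were made with TruSeq stranded total RNA reagents and RiboZero Gold, then sequenced to 54 base reads on a GAIIx, per the labels' protocols. Reads were trimmed with Trimmomatic, aligned with STAR to hg19 and assigned to genes with featureCounts, per the submitters' processing notes, and the versions of these tools are not given in the sources used here. For Reh, RS411, RCH and SEM the authors deposited raw read counts per gene, which were used here. The normalized signal values that the authors deposited for every line are read counts divided by 1 factor per library, and the tool that set the factor is not given in the sources used here. For 697 only these values were used. Dividing them by the value of a single read gave whole reads for 100% of the values above 0, within a tolerance of 0.001 reads. The normalized tables of the knockdown lines hold only part of the genes and served for an alternative. The Reh tables also hold a replicate numbered 3 of each arm, which matches none of the samples and was not used.

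Genes were handled by the names in the tables, with WHSC1 given as NSD2 and WHSC1L1 as NSD3. The raw Reh counts, listed by Ensembl identifier, took the symbols of genes with identical reads in the authors' normalized values, which named all 15793 genes with at least 50 reads, and of 15350 with a current symbol on both sides 15241 had the same symbol. In each knockdown line 27 gene names had turned into dates and were left out, with 0.214% of the reads in RS411, 0.247% in RCH and 0.230% in SEM. Gene spans came from a GRCh38 RefSeq table and served for lengths alone.

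Counts were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F-tests, with all arms of a line in 1 fit, filterByExpr by arm, TMM factors and robust dispersions. The 697 values were tested with limma 3.58.1 (eBayes with trend) on log2(normalized count + 1) for genes with a mean of at least 10. A joint edgeR fit of the NT and sh2 libraries of the knockdown lines, on 19573 genes, tested the mean response and, with 2 degrees of freedom, the difference between lines. P-values were adjusted by Benjamini and Hochberg within each comparison, with calls at an adjusted p under 0.05. Levels are CPM, or for 697 the authors' normalized counts, as mean ± SD, and log2 fold changes carry standard errors. Overlaps of called genes were set against n1 × n2 / N, and where 2 comparisons share controls against 10 simulations per line of unchanged groups. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.

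The comparisons, tests, gene lists, naming rule and most alternatives were chosen before the data were examined. Sets of genes were tested with camera (limma, preset correlation 0.01 between genes), adjusted over 27 lists within each of the 12 comparisons, and again with an estimated correlation. The lists covered H3K36 and H3K27 methylation enzymes and readers, the glucocorticoid receptor and its response genes, thiopurine, cytarabine and antifolate handling, DNA mismatch repair and damage signalling, ABC drug transporters, B-lymphoid identity, stem and progenitor genes, the BCL2 family, p53 targets, S phase, G2 and M phase, MYC and ribosome biogenesis, MAPK feedback and immediate early genes, and adhesion and migration receptors. The others were neural adhesion and signalling genes, interferon response, integrated stress response, unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, class II antigen presentation, replication-dependent histones, mitochondrially encoded transcripts, and markers of T and NK, myeloid, erythroid and megakaryocytic, and stromal and epithelial cells. CD24, CD99 and PECAM1 were matched to no gene in the tables.

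Named genes were NSD2 and, in EK versus EV and sh2 versus NT, the 6 highest and 6 lowest log2 fold changes among called genes with at least 5 CPM (697: 100 normalized counts) in the higher arm and no overlap between arms, leaving out clones, small RNAs and similar names. In other comparisons they were the 3 highest and 3 lowest. Some genes that this rule names are not reported here. Up to 2 called members per list with the smallest adjusted p were named, any list member could serve as an example, and so were up to 6 genes per direction called alike in all 3 sh2 comparisons or oppositely in EK and in sh2 of at least 2 lines.

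Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no or a stricter low-count filter, calls of at least 2-fold, the 2 compared arms alone, the replicate number as a block, limma on normalized values, other pseudocounts, edgeR on the recovered 697 reads, and leaving out each library. The edgeR fit of recovered reads with a block and the left-out libraries for list tests were added after the data were seen. Libraries were taken as paired by number where every one of at least 3 same-numbered pairs of changes correlated above 0.1, which Reh has too few pairs to meet. This held in 697 (0.42 to 0.60), RS411 (0.14 to 0.34), SEM (0.12 to 0.31) and RCH sh5 (0.25 to 0.64), not in RCH sh2 (0.12, 0.17 and -0.07).

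On data simulated from these samples, edgeR or limma called 54% of genes changed 2-fold in Reh, 58% in 697, 74% in RS411, 58% in RCH and 96% in SEM, together with 17, 7, 12, 10 and 16 unchanged genes. The biological coefficient of variation was 0.167, 0.215, 0.127, 0.232 and 0.090 in the same order.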

Results

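RNA was sequenced from 42 samples of 5 B-cell acute lymphoblastic leukaemia (B-ALL) lines in which NSD2, the enzyme that dimethylates lysine 36 of histone H3, had been raised or lowered. Reh and 697 cells carried an empty vector (EV), a vector for wild-type NSD2 (WT) or a vector for NSD2 with the E1099K substitution (EK), in 2 replicates per arm for Reh and 3 for 697. The lines titled RS411 (RS4;11), RCH (RCH-ACV) and SEM carried a non-targeting short hairpin (NT) or one of the hairpins sh2 and sh5, in 3 replicates per arm. The series text describes sh2 as the NSD2 knockdown, while sh5 appears only in the sample titles. The title of the series places the EK substitution at relapse and names drug resistance and dependence on the cell context as its subject. Total reads assigned to genes ran from 23688482 to 27244031 per library in Reh, from 27826387 to 67796769 in RS411, from 21941718 to 55001132 in RCH and from 32583013 to 39562010 in SEM. In 697 the reads recovered from the normalized counts ran from 40664735 to 57179806. Nothing in the labels says that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. A gene is called below when its adjusted p was under 0.05.

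NSD2, listed in the count tables under its older symbol WHSC1, followed the labels in all 5 lines. In Reh its transcript rose from 578.5 ± 2.92 CPM (reads scaled to equal library totals) with EV (SD, n = 2) to 1692 ± 77.2 with WT and 1682 ± 211 with EK. The log2 fold changes were 1.55 ± 0.13 (SE, adjusted p = 0.0135) and 1.54 ± 0.13 (adjusted p = 0.0168). In 697 it rose from 9767 ± 1770 normalized counts with EV (SD, n = 3) to 93070 ± 15600 with WT and 85910 ± 15600 with EK, by 3.26 ± 0.18 (adjusted p = 2.61e-05) and 3.14 ± 0.18 (adjusted p = 6.56e-05). In SEM it fell from 343.5 ± 18.1 CPM with NT to 172.8 ± 6.62 with sh2 and 141.7 ± 8.10 with sh5 (SD, n = 3), by log2 changes of -0.99 ± 0.06 (adjusted p = 8.92e-09) and -1.28 ± 0.06 (adjusted p = 1.87e-09). In RS411 the means were 307.8 ± 20.0 CPM with NT, 188.8 ± 56.4 with sh2 and 173.1 ± 34.6 with sh5. The log2 change with sh2, -0.71 ± 0.21, did not pass the test over all genes (adjusted p = 0.118), nor did that with sh5, -0.83 ± 0.21 (adjusted p = 0.164). In RCH the means were 341.1 ± 12.8, 199.6 ± 55.1 and 195.5 ± 39.3 CPM, and the changes of -0.77 ± 0.21 with sh2 (adjusted p = 0.0952) and -0.80 ± 0.21 with sh5 (adjusted p = 0.508) did not pass either. These outcomes depended on the analysis. DESeq2 called NSD2 lower in RS411 sh2, RS411 sh5 and RCH sh2, and the fits without sh2 replicate 3 called it in both sh2 arms. It was also called without the low-count filter in RCH sh2 and sh5, and with the 2 arms alone in RS411 sh5. Every sh2 and sh5 library nevertheless lay below every NT library of its line. For this an exact two-sided permutation test of 3 against 3 gives its smallest possible p, 0.1. The sh2 arms of RS411 and RCH were uneven, at 155.3, 157.2 and 253.9 CPM in RS411 replicates 1 to 3 and at 141.9, 205.3 and 251.7 CPM in RCH.

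**Figure D1:**
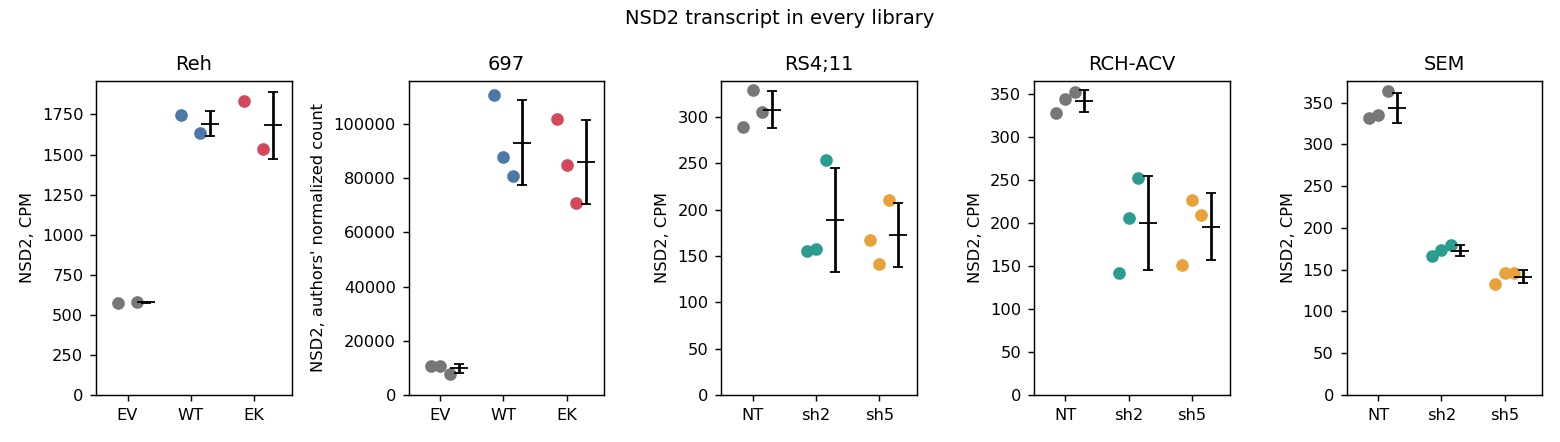
NSD2 transcript in every library of the 5 lines, in CPM or, for 697, in the authors' normalized counts, with points for libraries and bars for the mean ± SD of each arm. WT and EK libraries lie above all EV libraries, and sh2 and sh5 libraries lie below all NT libraries of their line. In RS411 and RCH sh2 replicate 3 is the highest of its arm.

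In Reh, EK raised 28 genes and lowered 6. MAGI1, a scaffold protein of cell junctions, rose from 0.350 ± 0.229 to 6.96 ± 0.70 CPM (SD, n = 2), a log2 change of 4.29 ± 0.40 (adjusted p = 0.0257). DPYD, the enzyme that starts the breakdown of uracil and thymine, rose 11.8-fold from 1.2 ± 0.3 to 14.3 ± 1.5 CPM (adjusted p = 0.0109). MB21D2, PCNXL2 and SOHLH2, a transcription factor of germ cells, rose by 3.67 ± 0.29, 3.26 ± 0.22 and 2.40 ± 0.27. Among the 6 genes that fell were DSC3, a cadherin of desmosomes, at -1.38 ± 0.11 (adjusted p = 0.0168), and PERP, a membrane protein of the same junctions, at -1.26 ± 0.13 (adjusted p = 0.0327). The others were GPRASP1 (-1.86 ± 0.23), RNF182 (-1.5 ± 0.2), MOXD1 (-1.21 ± 0.14) and FAM129A (-1.2 ± 0.1).

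By fixed gene list, 1 of 17 tested neural adhesion and signalling genes rose in Reh with EK. It was ROBO1, an axon guidance receptor, at 18.0 ± 0.50 against 3.66 ± 0.78 CPM (2.30 ± 0.19, adjusted p = 0.0168), and adjusted over the list alone 7 members were higher and 4 lower. Of 24 genes of DNA mismatch repair and damage signalling, LIG4, the ligase that seals double-strand breaks, rose 2.22-fold (adjusted p = 0.0397), also the only call adjusted over the list alone. NSD2 itself was the only called member of the list of H3K36 and H3K27 methylation enzymes and readers, among 26 tested, and no other list had a called member. No list passed camera's test in this comparison (neural list adjusted p = 0.151). In all, 34 of 15972 genes were called between EK and EV, against 982 at an unadjusted p under 0.05. The count rested on every library, as it came to 0 without either EV library, 3 without EK replicate 1 and 4 without EK replicate 2. It was 210 with DESeq2 (111 higher and 99 lower), 329 without the filter on low counts (177 and 152) and 7 when only the EK and EV libraries were fitted. With the replicate number as a block, for which Reh has too few pairs, it was 1027 (523 and 504). FRG2B and FRG2C, both called higher and mentioned here after their values were seen, are near copies of each other, so their values are uncertain.

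Wild-type NSD2 raised 30 genes and lowered 5 in Reh. MAGI1 rose by 4.35 ± 0.40 (adjusted p = 0.022) and ZNF536, a zinc finger protein of the nervous system, by 3.83 ± 0.25 (adjusted p = 0.00763). DSC3 fell by 1.68 on the log2 scale, RNF182 by 1.56 and PERP by 1.17. The remaining 2 genes that fell, ERBB4 (-4.66 ± 0.53) and SOCS2 (-1.09 ± 0.11), lie outside the naming rule and were chosen after their values were seen. With WT 35 genes were called, against 793 at an unadjusted p under 0.05. That count was 0 without EV replicate 1, 7 without EV replicate 2, 8 without WT replicate 1 and 4 without WT replicate 2. It was 139 with DESeq2, 237 without the low-count filter and 8 in the fit of those 2 arms alone. The replicate block, for which Reh has too few pairs, gave 629 (378 higher and 251 lower). The T and NK cell markers list was called higher (adjusted p = 0.0489, median 0.39, 7 tested, 0 called members over all genes or adjusted over the list alone), but adjusted p = 0.955 with an estimated correlation, 0.172 without EV replicate 2 and 0.143 without WT replicate 1.

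In Reh edgeR called 0 genes between EK and WT, with 260 at an unadjusted p under 0.05. DESeq2 called 2 and edgeR without the low-count filter 18. With the replicate number as a block edgeR called 71, 27 higher and 44 lower. The 2 pairs are too few to show that the numbers pair the Reh libraries. NSD2 levels differed by -0.01 ± 0.12 on the log2 scale. The mitochondrially encoded transcripts (13 tested, median 0.30, adjusted p = 0.000361) and the MYC and ribosome biogenesis genes (28 tested, median 0.21, adjusted p = 0.00865) were called higher with EK as lists, with 0 called members each over all genes and adjusted over the list alone. Both calls were lost at adjusted p = 0.996 with an estimated correlation, and the MYC list gave 0.546 without WT replicate 2 and 0.739 with the opposite sign without EK replicate 1. Of the genes called against EV, 26 were higher and 3 (RNF182, PERP and DSC3) lower in both EK and WT, where independent lists would share 0.0526 and 0.00188. Unchanged groups with the same EV libraries shared up to 3 calls in 10 simulations, so the 3 lower genes alone show no excess. The EK and WT changes correlated at 0.775 across 15972 genes (covariance 0.146), against a mean of 0.49 (covariance 0.0578) in 10 simulations of unchanged groups that shared the EV libraries. With 2 EV libraries the controls could not be split, so part of the excess may come from sharing them.

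In 697, EK raised 27 genes and lowered 1. NEO1, a receptor for netrins, rose from 17.1 ± 3.12 to 281.3 ± 30.7 normalized counts (SD, n = 3), a log2 change of 3.97 ± 0.24 (adjusted p = 6.56e-05). PTPRK, a receptor tyrosine phosphatase, rose 8.36-fold (3.06 ± 0.25, adjusted p = 0.000609), MAP2, a microtubule protein of dendrites, 5.60-fold (2.48 ± 0.31, adjusted p = 0.00858) and TANC2, a postsynaptic scaffold, 11.0-fold (3.46 ± 0.42, adjusted p = 0.00819). The zinc finger gene ZNF717 rose from 7.46 ± 3.44 to 309.7 ± 130 (5.18 ± 0.59, adjusted p = 0.00694) and C14orf37 from 19.6 ± 6.16 to 111.2 ± 17.4 (adjusted p = 0.00694). The single gene that fell was AL161772.1, from 62.3 ± 9.09 to 13.9 ± 4.54 (-2.13 ± 0.34, adjusted p = 0.0472), which lies outside the naming rule and was chosen after its values were seen.

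Several lists shifted together in 697 with EK although NSD2 was the only member of any list that passed over all genes. The replication-dependent histones lay lower (23 tested, median -0.33, adjusted p = 4.86e-12), as did glycolysis and hypoxia genes (26 tested, median -0.28, adjusted p = 3.4e-06) and cholesterol synthesis genes (24 tested, median -0.25, adjusted p = 2.53e-06). S phase genes (30 tested, median -0.18, adjusted p = 0.000168) and G2 and M phase genes (30 tested, median -0.26, adjusted p = 0.000362) lay lower too. Each of these had adjusted p = 0.688 with an estimated correlation, and adjusted over the list alone only 1 cholesterol synthesis gene was called, lower. The cycle calls were lost without EV replicate 1, at 0.351 for S phase and 0.43 for G2 and M phase, and the latter also without EK replicate 3, at 0.136. The p53 targets lay higher (25 tested, median 0.09, adjusted p = 0.0189, with 2 called higher adjusted over the list alone), with adjusted p = 0.688 with an estimated correlation, 0.837 without EK replicate 1, 0.0744 without EV replicate 2 and 0.0768 without EV replicate 3. The mitochondrially encoded transcripts were called higher (median 0.69, adjusted p = 0.0473; 0.688 with an estimated correlation), and EK replicate 2 held 0.732% of its reads in them, against 0.218% to 0.370% in the other 8 libraries of the line. Without that library the list changed sign (adjusted p = 0.827), and it was also lost without EV replicate 1 (0.351) and EV replicate 3 (0.0828) and with median-centred values (0.0568).

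Weaker shifts in 697 with EK were those of thiopurine, cytarabine and antifolate handling (median -0.12, adjusted p = 0.0364), DNA mismatch repair and damage signalling (median -0.12, adjusted p = 0.0473) and MYC and ribosome biogenesis (median -0.12, adjusted p = 0.037). All 3 lay lower with no called member over all genes or adjusted over the list alone, and each had adjusted p = 0.688 with an estimated correlation. The thiopurine call was lost without EK replicate 2 (0.133), EK replicate 3 (0.129) and EV replicate 1 (0.585), and the mismatch repair call without EK replicate 1 (0.0898), EK replicate 2 (0.436) and EV replicate 1 (0.78). The MYC call was lost without EK replicate 2 (0.75), EV replicate 1 (0.254) and EV replicate 3 (0.0573) and with the replicate block (0.0565). The stricter minimum lost all 3, at 0.0514, 0.0514 and 0.0515. The replicate block added calls of stem and progenitor genes (0.0373) and adhesion and migration receptors (0.0498) as lower, and of the integrated stress response (0.0259) and class II antigen presentation (0.0292) as higher.

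Between EK and EV 28 of 16310 genes were called in 697 by limma on log2(normalized count + 1), with 796 at an unadjusted p under 0.05. Fold changes on that scale understate the change of low genes. With the replicate number as a block, which pairs the libraries in this line, 161 genes were called, 93 higher and 68 lower. On the recovered reads edgeR called 24, and with the block 111 higher and 78 lower. A minimum mean of 50 normalized counts gave 17 calls, the 2 arms alone 9, and the fits without EK replicate 3 and without EV replicate 2 gave 18 each.

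With WT, 697 cells raised NEO1 by 4.25 ± 0.24 (adjusted p = 2.61e-05), ZNF717 by 5.46 ± 0.59 (adjusted p = 0.00303) and SCN3A, a voltage-gated sodium channel, from 4.17 ± 1.11 to 202.1 ± 24.3 normalized counts (5.31 ± 0.26, adjusted p = 1.63e-05). All 31 genes called between WT and EV were higher, and 27 of them were also called higher with EK, where independent lists would share 0.0513 and simulated unchanged groups shared 0. The 2 sets of changes correlated at 0.73 across 16310 genes (covariance 0.089), against 0.498 (0.0519) in 10 simulations that shared the EV libraries, and part of that excess may come from the shared controls. As lists, the p53 targets lay higher (median 0.17, adjusted p = 0.000165), and glycolysis and hypoxia genes (median -0.26, adjusted p = 1.39e-07), cholesterol synthesis genes (median -0.17, adjusted p = 1.57e-05) and replication-dependent histones (median -0.12, adjusted p = 0.000709) lay lower. All 4 had adjusted p = 0.887 with an estimated correlation and no called member over all genes, and adjusted over the list alone 1 cholesterol synthesis gene was lower. The cholesterol call was lost without EV replicate 2 (0.0655), and the histone list changed sign without EV replicate 1 (0.815). The 31 calls, with 468 genes at an unadjusted p under 0.05, became 176 with the replicate block (101 higher and 75 lower), 205 with edgeR and the block (114 and 91), 18 with the stricter minimum, 20 without EV replicate 1, 19 without EV replicate 2 and 18 without either WT replicate 1 or WT replicate 2.

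Other lists passed more narrowly in 697 with WT, none with a member called over all genes. Interferon response genes (median 0.12, adjusted p = 0.0369) and integrated stress response genes (median 0.07, adjusted p = 0.0376) lay higher and MYC and ribosome biogenesis genes lower (median -0.06, adjusted p = 0.0376), with no member called adjusted over the list alone and adjusted p = 0.887 with an estimated correlation for each. The interferon call was lost without EV replicate 1 (0.0855), EV replicate 2 (0.439), WT replicate 1 (0.186) and WT replicate 3 (0.239), and the stress call without EV replicate 1 (0.382), EV replicate 3 (0.261) and WT replicate 2 (0.855). The MYC call was lost without EV replicates 1 (0.381), 2 (0.0545) and 3 (0.0552) and WT replicates 1 (0.123), 2 (0.103) and 3 (0.0557). The 4 myeloid markers tested lay higher (median 0.36, adjusted p = 0.0125; adjusted p = 0.576 with an estimated correlation), 1 of them adjusted over the list alone, but not without EV replicate 1 (0.0855), EV replicate 2 (0.0655) or WT replicate 3 (0.141), nor with the stricter minimum (0.393). The replicate block added stem and progenitor genes (0.0233), G2 and M phase genes (0.0303) and adhesion receptors (0.0303) as lower and class II genes (0.0228) as higher.

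No gene separated EK from WT in 697. limma called 0 genes with 118 at an unadjusted p under 0.05, edgeR on the recovered reads called 0, and both called 0 with the replicate block, while 1 gene was called without EK replicate 2. NSD2 levels differed by -0.12 ± 0.18. As lists the replication-dependent histones (median -0.22, adjusted p = 1.2e-08) and S phase genes (median -0.14, adjusted p = 0.000153) lay lower in EK than in WT, with no called member over all genes or adjusted over the list alone, and adjusted p = 0.938 with an estimated correlation for each. The S phase call was lost without EK replicate 3 (0.0798) and without WT replicate 1 (0.116). G2 and M phase genes (adjusted p = 0.00809) and thiopurine handling (adjusted p = 0.0322) lay lower and mitochondrially encoded transcripts (adjusted p = 0.00557) and stromal markers (adjusted p = 0.0322) higher, each with adjusted p = 0.938 with an estimated correlation and no called member on either basis. The G2 and M phase call was lost without EK replicates 1 (0.0642) and 3 (0.624) and WT replicates 1 (0.299) and 2 (0.638), and the thiopurine call without EK replicates 2 (0.273) and 3 (0.187) and WT replicates 1 (0.17) and 2 (0.0951). The stromal call was lost without EK replicates 2 (0.558) and 3 (0.0849) and WT replicate 1 (0.241) and with the stricter minimum (0.172), and the mitochondrial list changed sign without EK replicate 2 (0.577) and was lost without WT replicate 1 (0.183). With the replicate block the neural list was called higher (0.0455). Of the genes called higher with EK in Reh and in 697, 18 and 21 were tested in both lines, and 1, NSD2, was called in both, where independent lists would share 0.0264.

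In RS411, sh2 raised 162 genes and lowered 124. SLC6A13, a transporter of the neurotransmitter GABA, rose from 0.724 ± 0.464 to 5.19 ± 1.61 CPM (SD, n = 3), a log2 change of 2.89 ± 0.45 (adjusted p = 0.0221). ZBTB46, a transcription factor known from dendritic cells, rose by 2.73 ± 0.26 (adjusted p = 0.00116), and the Wnt ligand WNT8A by 2.59 ± 0.43 (adjusted p = 0.0335). The death receptor TNFRSF25 rose by 2.37 ± 0.37 (adjusted p = 0.0192) and DUSP6, a phosphatase that turns off ERK, by 2.20 ± 0.39 (adjusted p = 0.0332). CABLES1, which binds cyclin-dependent kinases, rose 6.63-fold (adjusted p = 0.00359). Genes that fell included ITGA2B, an integrin of platelets, from 25.1 ± 1.38 to 8.0 ± 3.0 CPM (-1.64 ± 0.23, adjusted p = 0.0191), AKR1C3, an enzyme of steroid metabolism (-1.42 ± 0.17, adjusted p = 0.00391), and ABCB4, a phospholipid transporter (-1.33 ± 0.26, adjusted p = 0.0401). LACC1 (-1.39 ± 0.27), SESN3 (-1.24 ± 0.22) and DNHD1 (-1.17 ± 0.22) also fell.

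Of 25 p53 targets tested in RS411, 4 rose with sh2 and none fell. They were SESN1 (1.11 ± 0.19), PHLDA3 (0.84 ± 0.18), ZMAT3 (0.86 ± 0.18) and RRM2B (0.36 ± 0.08), and the same number passed adjusted over the list alone. The list was called higher (median 0.10, adjusted p = 0.000889), with adjusted p = 0.509 with an estimated correlation. Of 22 stem and progenitor genes, GATA2 (2.78 ± 0.56) and the adhesion receptor CD44 (0.81 ± 0.16) rose, 5 were higher and 1 lower adjusted over the list alone, and the list lay higher (median 0.15, adjusted p = 0.000889; adjusted p = 0.715 with an estimated correlation). Of 32 genes of B-lymphoid identity 3 rose, namely IRF8 (0.89 ± 0.13), the recombinase gene RAG2 (0.37 ± 0.07) and BLNK, with 4 higher and 3 lower adjusted over the list alone and no call of the list (adjusted p = 0.446). The T and NK cell markers CD7 and GATA3 (1.44 ± 0.28) rose among 9 tested, 3 higher and 1 lower adjusted over the list alone, again without a call of the list (adjusted p = 0.0961). Cholesterol synthesis genes lay lower as a list (24 tested, median -0.44, adjusted p = 6.6e-07) with no called member over all genes or adjusted over the list alone, and adjusted p = 0.769 with an estimated correlation. Glycolysis and hypoxia genes also lay lower (median -0.21, adjusted p = 0.015, 7 lower adjusted over the list alone), with adjusted p = 0.845 with an estimated correlation, 0.155 without NT replicate 3 and 0.238 without sh2 replicate 2. ASNS, which makes asparagine, fell by 0.90 on the log2 scale as the only called member of the integrated stress response list.

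In all 286 of 17165 genes were called between sh2 and NT in RS411, with 3124 at an unadjusted p under 0.05. Upper-quartile scaling gave 121 higher and 150 lower. The replicate block, which pairs the libraries of this line, gave 2495 calls, DESeq2 929, the fit without a low-count filter 1281, the stricter filter 186 and the fit of the 2 arms alone 66. Every library moved the count, to 11 without NT replicate 1, 22 without NT replicate 2, 45 without NT replicate 3, 25 without sh2 replicate 1, 32 without sh2 replicate 2 and 1560 without sh2 replicate 3, the library with the highest NSD2 of its arm. At least 2-fold changes made up 142 of the calls.

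With sh5, RS411 cells raised PCDH9, a protocadherin, from 0.213 ± 0.095 to 11.5 ± 7.29 CPM (SD, n = 3; 5.78 ± 0.57, adjusted p = 0.00595), WNT8A 12.2-fold (adjusted p = 0.017) and SLC6A13 7.56-fold (adjusted p = 0.0253). KAZALD1 (-0.62 ± 0.08, adjusted p = 0.00963) and CMTM3 (-0.61 ± 0.09, adjusted p = 0.0152) fell, and so did ZNF37BP (-0.40 ± 0.08), which was chosen after its values were seen. HLA-DQA1 was the called member among 16 tested genes of antigen presentation on major histocompatibility complex class II, 5 were higher adjusted over the list alone, and the list lay higher (median 0.17, adjusted p = 8.06e-05; adjusted p = 0.416 with an estimated correlation). Stem and progenitor genes also lay higher (median 0.08, adjusted p = 8.06e-05), BMI1 being the called member of 22 and 7 being higher adjusted over the list alone, with adjusted p = 0.64 with an estimated correlation. S phase genes lay lower (adjusted p = 0.0425; adjusted p = 0.95 with an estimated correlation) and unfolded protein response genes higher (adjusted p = 0.0425; adjusted p = 0.64 with an estimated correlation), with no called member on either basis. The S phase call was lost without NT replicates 1 (0.35) and 3 (0.224) and sh5 replicate 2 (0.157), and the other without NT replicates 1 (0.15) and 2 (0.132) and sh5 replicates 1 (0.152) and 3 (0.0712). Both were lost with RLE scaling (0.0532 each), and the unfolded protein response also with the stricter filter (0.0944). The replicate block added replication-dependent histones as lower (0.0392).

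Between sh5 and NT 82 genes were called in RS411, 79 higher and 3 lower, with 1932 at an unadjusted p under 0.05. The count was 929 with the replicate block (597 higher and 332 lower), 314 with DESeq2 (243 and 71) and 578 without the low-count filter (413 and 165). It was 48 with the stricter filter, 43 at 2-fold or more and 197 in the fit of the 2 arms alone. Left-out libraries gave 5 without NT replicate 1, 15 without NT replicate 2, 28 without NT replicate 3, 12 without sh5 replicate 1 and 42 without sh5 replicate 3. With sh2 it shared 28 higher genes and 1 lower gene (ZNF37BP), where independent lists would share 0.746 and 0.0217 and simulated unchanged groups shared 0, and the changes correlated at 0.55 (covariance 0.101), against 0.513 (0.0381) in simulations of unchanged groups with shared NT libraries, from which part of the excess may come.

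In RCH, sh2 raised 205 genes and lowered 34. MME, the neprilysin gene, rose from 10.8 ± 6.18 to 240.3 ± 83.9 CPM (SD, n = 3; 4.48 ± 0.54, adjusted p = 0.00728), and MS4A1, which encodes CD20, from 1.94 ± 1.06 to 63.7 ± 57.0 (5.07 ± 0.92, adjusted p = 0.0395). SUCNR1, the succinate receptor, rose by 6.05 ± 0.82 (adjusted p = 0.0105), the actin-binding calponin CNN2 by 5.89 ± 0.77 (adjusted p = 0.0105), the homeobox gene HMX2 by 4.78 ± 0.48 (adjusted p = 0.00516), NACC2 by 4.72 ± 0.50 and CDC42EP1 by 4.76 ± 0.55. CNR1, a cannabinoid receptor, fell from 26.7 ± 3.78 to 3.65 ± 2.35 CPM (-2.86 ± 0.47, adjusted p = 0.0218), with NELL2 (-3.22 ± 0.63), DPYSL3, a protein of growing axons (-2.86 ± 0.43), the receptor phosphatase PTPRM (-2.25 ± 0.43) and RIMKLA (-2.12 ± 0.43). SPRY4, a feedback inhibitor of receptor tyrosine kinases, fell by 2.47 and the transcription factor ETV4 by 1.89 on the log2 scale. They were the called members among 26 MAPK feedback and immediate early genes, of which 3 were higher and 4 lower adjusted over the list alone and the list was not called (adjusted p = 0.553).

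Class II antigen presentation stood out among the RCH lists. Of 17 genes 7 rose, 0 fell and 10 were not called, and 14 rose adjusted over the list alone. HLA-DQB1 rose from 10.7 ± 1.69 to 33.0 ± 7.24 CPM (1.62 ± 0.23, adjusted p = 0.0105), and HLA-DQA1 from 42.6 ± 2.96 to 112.6 ± 20.7 (1.40 ± 0.20, adjusted p = 0.0105). HLA-DRB1 rose by 0.91 ± 0.17, while the coactivator CIITA had 0.46 ± 0.20 (adjusted p = 0.258). The list was called higher (median 0.69, adjusted p = 3.2e-10; adjusted p = 0.487 with an estimated correlation). HLA-DRB1 and HLA-DRB5 share much of their sequence, so their separate values are uncertain. Interferon response genes lay higher (33 tested, median 0.61, adjusted p = 6.55e-08; adjusted p = 0.678 with an estimated correlation), with USP18 (2.48 ± 0.44) and IFI44 (2.26 ± 0.39) called and 14 higher adjusted over the list alone. Genes of B-lymphoid identity lay higher (32 tested, median 0.35, adjusted p = 0.000196; adjusted p = 0.678 with an estimated correlation), MME and MS4A1 being called and 8 higher and 1 lower adjusted over the list alone. T and NK cell markers lay higher (12 tested, median 0.97, adjusted p = 0.000501; adjusted p = 0.168 with an estimated correlation), with TCF7 (4.17 ± 0.64) called and 5 higher adjusted over the list alone, but the stricter filter left adjusted p = 0.0672. MYC and ribosome biogenesis genes lay lower (28 tested, median -0.52, adjusted p = 0.000196; adjusted p = 0.678 with an estimated correlation), with no called member and 1 higher and 1 lower adjusted over the list alone.

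Further lists passed in RCH with sh2 but depended on single libraries, each with adjusted p = 0.678 with an estimated correlation unless given. G2 and M phase genes (median -0.20, adjusted p = 0.00125) and S phase genes (median -0.18, adjusted p = 0.0115) lay lower with no called member on either basis. The former call was lost without sh2 replicate 1 (0.0543) and the latter without NT replicate 2 (0.163) and sh2 replicate 3 (0.101). Neural adhesion and signalling genes lay lower (18 tested, median -0.73, adjusted p = 0.0115, 1 higher and 5 lower adjusted over the list alone), but not without NT replicate 1 (0.134) or sh2 replicate 1 (0.0543). Integrated stress response genes lay higher (median 0.53, adjusted p = 0.0024), with no called member on either basis, but not without NT replicate 1 (0.106) or sh2 replicate 2 (0.0542). Replication-dependent histones lay lower (median -0.23, adjusted p = 0.0486; adjusted p = 0.723 with an estimated correlation), but not without NT replicates 2 (0.468) and 3 (0.161) or sh2 replicates 1 (0.414) and 3 (0.101), with RLE scaling (0.0509) or with the stricter filter (0.0672). Single list members that rose were FLT3 (1.37 ± 0.20) and TAL1 (3.37 ± 0.64), regulators of blood progenitors, BIK (1.30 ± 0.24), which promotes apoptosis, and LIG4 (1.19 ± 0.23). So did the axon guidance receptor ROBO2 (2.37 ± 0.46), ERN1, a sensor of unfolded proteins (1.5 ± 0.3), and ZMAT3 (1.00 ± 0.21).

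Between sh2 and NT 239 of 17468 genes were called in RCH, with 3273 at an unadjusted p under 0.05. Left-out libraries gave 15 without NT replicate 2, 25 without NT replicate 3, 74 without sh2 replicate 1, 43 without sh2 replicate 2 and 620 without sh2 replicate 3 (345 higher and 275 lower). DESeq2 called 1077 (669 and 408), edgeR without a low-count filter 1937 (938 and 999), and limma on the authors' normalized values 156.

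With sh5, RCH gave 4 called genes, all higher and all also higher with sh2. They were COL8A2, a collagen chain, from 6.45 ± 1.28 to 29.8 ± 4.62 CPM (SD, n = 3; 2.21 ± 0.25, adjusted p = 0.0374), TNFRSF25 (2.16 ± 0.28, adjusted p = 0.0468), RNF144B (1.36 ± 0.17, adjusted p = 0.0468) and ABHD12B, which falls outside the naming rule and was chosen after its values were seen. Independent lists would share 0.0469 genes, and simulated unchanged groups shared 0. As lists, interferon response genes (median 0.30, adjusted p = 8.85e-09) and class II genes (median 0.18, adjusted p = 3.34e-05) lay higher, with no called member over all genes or adjusted over the list alone and adjusted p = 0.638 with an estimated correlation. The class II call was lost without sh5 replicate 1 (0.0562). Integrated stress response genes also lay higher (median 0.54, adjusted p = 5.2e-06; adjusted p = 0.638 with an estimated correlation), again with no called member on either basis, but at 0.369 without sh5 replicate 1.

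Further lists passed in RCH with sh5, each with adjusted p = 0.638 with an estimated correlation unless given and no member called over all genes. Stem and progenitor genes lay higher (adjusted p = 0.00298, 3 higher adjusted over the list alone), lost without NT replicate 3 (0.0663), and DNA mismatch repair genes higher (adjusted p = 0.0164), lost without NT replicate 3 (0.334) and sh5 replicate 3 (0.178). MAPK feedback genes (adjusted p = 0.00694, 1 lower adjusted over the list alone), neural genes (adjusted p = 0.00694, 2 lower adjusted over the list alone) and mitochondrially encoded transcripts (adjusted p = 0.00674) lay lower. These were lost without NT replicate 3 (0.482) and sh5 replicate 1 (0.0653), without NT replicate 1 (0.292), and without NT replicate 3 (0.1) and sh5 replicate 3 (0.241), in that order. Replication-dependent histones lay higher (adjusted p = 0.00876; adjusted p = 0.83 with an estimated correlation), changed sign without NT replicate 1 (0.593) and were lost without sh5 replicate 3 (0.142). The replicate block added glycolysis and hypoxia genes as lower (0.0174). At an unadjusted p under 0.05 there were 706 genes, the replicate block called 46, DESeq2 91, edgeR without a low-count filter 199, the stricter filter 0 and upper-quartile scaling 1. The count was 1 without NT replicate 1, 0 without NT replicate 2, NT replicate 3, sh5 replicate 1 or sh5 replicate 3, and 2 without sh5 replicate 2. The changes with sh2 and sh5 correlated at 0.66 (covariance 0.175), against 0.484 (0.0579) in simulations, and part of the excess may come from the shared NT libraries.

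In SEM, sh2 changed 4760 genes. MMP16, a membrane-bound matrix metalloprotease, fell from 25.4 ± 2.41 to 0.255 ± 0.152 CPM (SD, n = 3; -6.61 ± 0.22, adjusted p = 4.59e-11). The transcription factor FOXP2 fell from 7.58 ± 0.55 to 0.110 ± 0.043 (-6.06 ± 0.27, adjusted p = 3.74e-10) and the neural cadherin CDH2 from 62.5 ± 3.16 to 3.56 ± 0.54 (-4.13 ± 0.10, adjusted p = 9.01e-13). FREM2, an extracellular matrix protein (-5.48 ± 0.25), MPDZ (-5.82 ± 0.28), CCSER1 (-5.37 ± 0.23) and RNF150, of which too few reads were left for a fold change, fell in the same way. Among the genes that rose, ANGPT1, a growth factor of the vessel wall, went from 11.0 ± 0.41 to 108.8 ± 9.69 CPM (3.31 ± 0.09, adjusted p = 2.98e-12). NES, an intermediate filament protein, went from 0.910 ± 0.120 to 11.9 ± 0.37 (3.71 ± 0.15, adjusted p = 1.19e-10). ANXA1, a glucocorticoid-induced anti-inflammatory protein, rose by 4.69 ± 0.28, NAPSB by 3.86 ± 0.16, RFX8 by 2.89 ± 0.19 and MICAL2, an oxidase of actin, by 2.83 ± 0.13.

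B-lineage genes of SEM moved mostly down and class II genes up. Of 33 genes of B-lymphoid identity 15 fell, 4 rose and 14 were not called, with the same counts adjusted over the list alone. MS4A1 (-4.22 ± 0.39), the surrogate light chain genes VPREB1 (-1.09 ± 0.09) and VPREB3 (-1.71 ± 0.13) and the transcription factors IRF4 (-1.17 ± 0.06) and EBF1 (-0.47 ± 0.06) fell, IRF8 rose (1.02 ± 0.05), and PAX5 had -0.03 ± 0.07 (adjusted p = 0.761). The list was called lower (median -0.25, adjusted p = 0.00876; adjusted p = 0.835 with an estimated correlation). Of 17 class II genes 13 rose and 0 fell, 14 adjusted over the list alone, including HLA-DQA1 (1.26 ± 0.11), HLA-DPA1 (0.55 ± 0.06) and CIITA (0.36 ± 0.08). The list was called higher (median 0.44, adjusted p = 1.87e-06; adjusted p = 0.384 with an estimated correlation). Of 10 myeloid markers 5 rose, among them CSF1R (1.32 ± 0.17) and ITGAM (1.16 ± 0.21), 0 fell and 6 rose adjusted over the list alone (median 0.47, adjusted p = 0.00508; adjusted p = 0.835 with an estimated correlation). LYZ, an abundant myeloid transcript, had 0.21 ± 0.41 (adjusted p = 0.761) with sh2, although it was called higher with sh5. The T and NK cell markers LCK (-1.14 ± 0.09) and ZAP70 (-1.05 ± 0.06), kinases of T cell receptor signalling, fell with 2 others of the 6 tested, 1 rose, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.0587). In the stem and progenitor list 4 of 21 rose, including LMO2 (1.46 ± 0.06), and 5 fell, including ERG (-0.40 ± 0.06) and ZNF521, of which hardly any reads were left. Adjusted over the list alone these were 5 and 5 (list adjusted p = 0.871).

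Cholesterol synthesis genes of SEM fell with sh2, 16 of 24 members being lower and 1 higher, with the same counts adjusted over the list alone. HMGCS1, which supplies the substrate of HMG-CoA reductase, fell from 525.6 ± 40.6 to 340.4 ± 7.86 CPM (-0.63 ± 0.07, adjusted p = 7.38e-06), MSMO1 by 0.44 and SREBF2, the regulator of the pathway, by 0.48 on the log2 scale. The list was called lower (median -0.23, adjusted p = 0.000783; adjusted p = 0.885 with an estimated correlation). MYC and ribosome biogenesis genes lay higher (11 of 27 rose and 0 fell, 12 adjusted over the list alone, median 0.18, adjusted p = 0.00478; adjusted p = 0.835 with an estimated correlation), for example CAD (0.34 ± 0.06) and MXD1, an antagonist of MYC (0.91 ± 0.10). Neural adhesion and signalling genes lay lower, with 7 of 14 lower and 4 higher, and 8 and 4 adjusted over the list alone. They included NRCAM from 7.52 ± 1.88 to 0.402 ± 0.123 CPM, and SLIT2, from 1.90 ± 0.27 to 0.047 ± 0.042 CPM. That list call (median -1.03, adjusted p = 0.0347; adjusted p = 0.835 with an estimated correlation) was lost with the replicate block (0.0615) and without NT replicate 3 (0.0763). The unfolded protein response (4 of 21 higher and 1 lower, also adjusted over the list alone) missed the threshold (adjusted p = 0.0565) and was called with the block (0.0067).

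Genes tied to drug handling and cell death moved both ways in SEM. ABCB1, the multidrug efflux pump, fell from 2.37 ± 0.49 to 0.338 ± 0.145 CPM (-2.82 ± 0.29, adjusted p = 3.22e-06) and ABCA3 rose (1.14 ± 0.12), among 10 ABC transporters with 2 higher and 3 lower (3 and 4 adjusted over the list alone). Of 15 BCL2 family genes, BCL2L11 (-0.56 ± 0.11) and BMF (-0.81 ± 0.09) fell and BID and BIK rose, all 4 proapoptotic (5 higher and 2 lower adjusted over the list alone). Of 23 genes of the glucocorticoid receptor and its response, 4 rose, such as SESN1 (1.31 ± 0.06), and 6 fell, such as IL7R, the interleukin 7 receptor (-0.51 ± 0.05), while the receptor gene NR3C1 had -0.05 ± 0.06 (adjusted p = 0.647). Adjusted over the list alone 5 rose and 6 fell. Of 29 genes of thiopurine, cytarabine and antifolate handling 7 rose, including the folate carrier SLC19A1 (0.49 ± 0.07) and SAMHD1 (0.45 ± 0.07), and 4 fell (8 and 6 adjusted over the list alone). DNA mismatch repair and damage signalling had 1 higher and 2 lower of 25, BRCA2 (-0.26 ± 0.06) and PARP1 (-0.19 ± 0.05) being lower, and 0 and 2 adjusted over the list alone. Among the H3K36 and H3K27 methylation enzymes and readers DNMT3B rose (0.82 ± 0.09) and 6 of 26 fell, NSD2, DNMT3A (-0.22 ± 0.06) and JARID2 among them, as they did adjusted over the list alone. None of these 6 lists was called (adjusted p from 0.615 to 0.971).

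The remaining lists of SEM were not called either. The p53 targets had 6 of 24 higher and 5 lower (MDM2 -0.35 ± 0.06), with 8 and 5 adjusted over the list alone. The interferon response had 8 higher (OAS2 0.99 ± 0.10) and 9 lower (RSAD2 -1.45 ± 0.20) of 33, with 8 and 10 adjusted over the list alone (each list adjusted p = 0.608). Adhesion and migration receptors had 11 higher, ITGA6 among them (1.84 ± 0.10), and 10 lower of 26, with 11 and 11 adjusted over the list alone. MAPK feedback and immediate early genes had 4 higher, such as FOSL1 (2.01 ± 0.28), and 2 lower, such as SPRY1 (-2.37 ± 0.19), of 26, with 3 and 2 adjusted over the list alone. Of 30 G2 and M phase genes 4 were lower, CDK1 and KIF11 among them, on either basis, and of 30 S phase genes none was called on either. Glycolysis and hypoxia had 2 higher and 3 lower of 27 (0 and 1 adjusted over the list alone), and the integrated stress response 1 higher (WARS 0.62 ± 0.11) and 3 lower of 23 on either basis. Replication-dependent histones and mitochondrially encoded transcripts had no called member on either basis, the erythroid and megakaryocytic markers had GP9 lower (-1.2 ± 0.3) of 3, and the stromal and epithelial markers PDGFRB higher (0.48 ± 0.08) of 6. Adjusted over the list alone the marker lists had 1 higher and 2 lower, and 2 higher and 1 lower. For the stem and progenitor list median (-0.02) and mean (-0.18) were negative while camera's direction was up. Median and mean differed in sign for ABC transporters (0.08 and -0.21), adhesion receptors (0.05 and -0.07), S phase (-0.01 and 0.01) and stromal markers (0.28 and -0.13). The medians of the thiopurine and integrated stress response lists turned negative under upper-quartile scaling (-0.04 and -0.01).

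With sh2 4760 of 17042 genes were called in SEM, 2298 higher and 2462 lower, with 6367 at an unadjusted p under 0.05. Upper-quartile scaling gave 1719 higher and 2941 lower, and at least 2-fold changes made up 1310 of the calls, 333 higher and 977 lower.

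**Figure D2:**
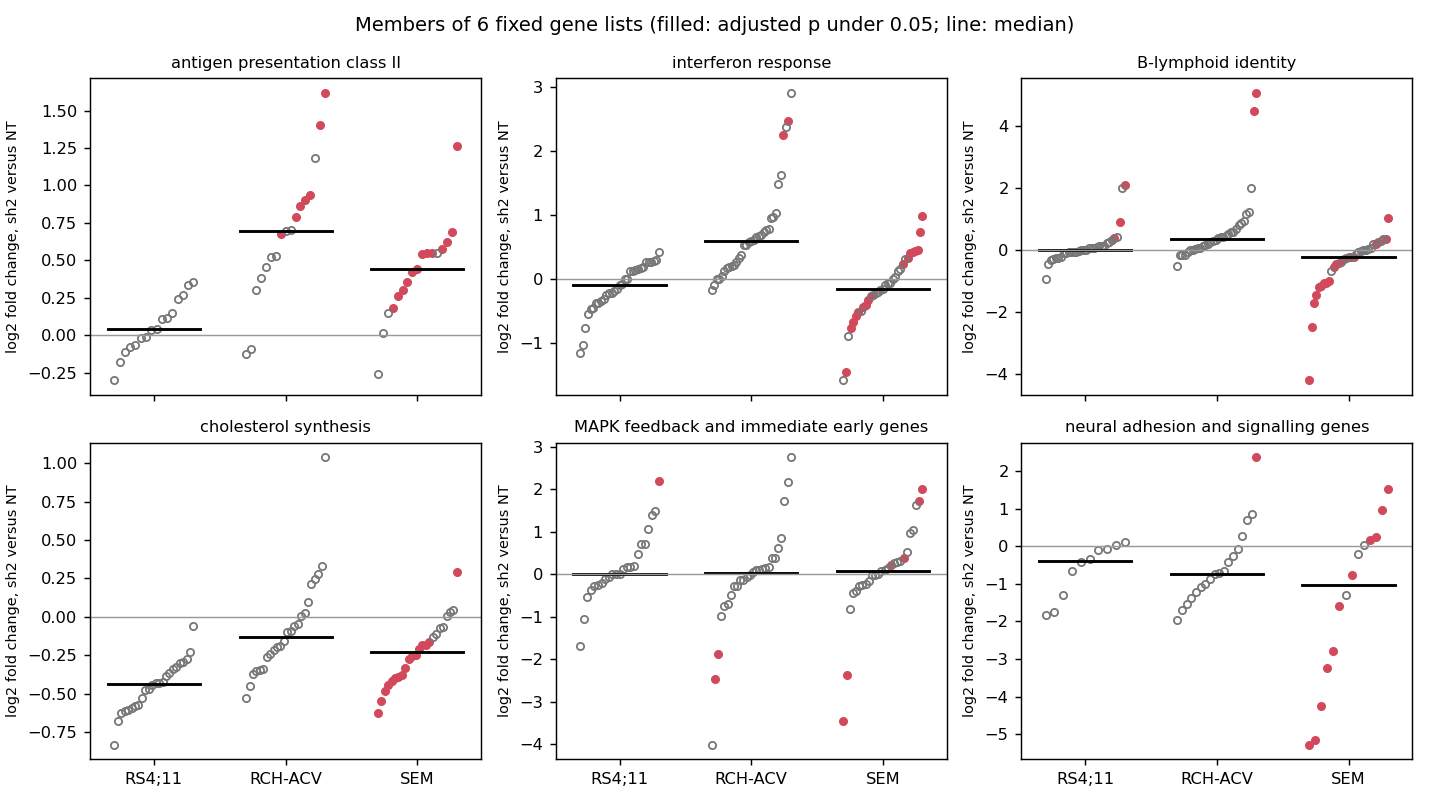
Log2 fold changes, sh2 versus NT, of the members of 6 fixed gene lists in RS411, RCH and SEM, one point per gene and a line at the median, with called genes filled. Class II genes have medians of 0.04, 0.69 and 0.44 in the 3 lines, the RS411 value turning to -0.01 under upper-quartile scaling.

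With sh5, SEM raised ENPP2, the lysophospholipase autotaxin, from 0.601 ± 0.205 to 10.6 ± 0.67 CPM (SD, n = 3; 4.14 ± 0.18, adjusted p = 9.87e-10), NAPSB by 4.01 ± 0.16 and CD226, an activating receptor of T and NK cells, by 3.30 ± 0.17. SCN3A (-3.65 ± 0.25), CCSER1 (-3.21 ± 0.18) and IGLL5 (-2.90 ± 0.17) fell. Of 17 class II genes 12 rose and 0 fell, 13 adjusted over the list alone (median 0.28, adjusted p = 5.17e-06; adjusted p = 0.445 with an estimated correlation). Of 33 genes of B-lymphoid identity 5 rose and 14 fell, 5 and 17 adjusted over the list alone, and the list missed the threshold (adjusted p = 0.0522) but was called with the replicate block (0.042). Cholesterol synthesis genes had 1 higher and 7 lower of 24, also adjusted over the list alone (adjusted p = 0.0522, and 0.0418 with the block). Of 10 myeloid markers 5 rose and 0 fell, also adjusted over the list alone (median 0.58, adjusted p = 0.0343; adjusted p = 0.798 with an estimated correlation), a call lost without sh5 replicate 2 (0.0528). Of 6 T and NK cell markers 2 fell, 3 adjusted over the list alone (median -0.38, adjusted p = 0.0393; adjusted p = 0.798 with an estimated correlation), a call lost without NT replicate 3 (0.118) and sh5 replicate 1 (0.083). The block also added MYC and ribosome biogenesis (0.0237), interferon response (0.0418) and unfolded protein response genes (0.0418) as higher, and glycolysis and hypoxia (0.00801) and MAPK feedback genes (0.0418) as lower.

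Between sh5 and NT 3623 genes were called in SEM, 1889 higher and 1734 lower, with 5572 at an unadjusted p under 0.05. The replicate block gave 5591, upper-quartile scaling 1408 higher and 2195 lower, and 890 calls were at least 2-fold. With sh2 it shared 1240 higher and 1263 lower genes, where independent lists would share 255 and 251 and simulated unchanged groups shared 0. The changes correlated at 0.767 (covariance 0.327), against 0.506 (0.0269) in simulations, and part of the excess may come from the shared NT libraries.

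Fits without the replicate block called few genes alike with sh2 in the 3 knockdown lines. With the block (2495 calls instead of 286 in RS411) the overlap was not counted. Few shared calls thus need not mean few shared responses. Of 14965 genes tested in all 3 lines, 9 were called higher with sh2 in each line and 1 lower. TLE2, a transcriptional corepressor, rose by 2.92 ± 0.47 in RS411, 3.37 ± 0.52 in RCH and 2.49 ± 0.25 in SEM, and CPT1A, which brings fatty acids into mitochondria, by 0.75 ± 0.13, 0.83 ± 0.11 and 2.04 ± 0.18. AIM1 rose by 1.41 ± 0.17, 1.34 ± 0.19 and 1.30 ± 0.14, and NPR1, a receptor for natriuretic peptides, by 2.21 ± 0.44, 2.52 ± 0.35 and 0.73 ± 0.20. GCNT1, a glycosyltransferase, rose by 0.71 ± 0.11, 1.30 ± 0.21 and 0.54 ± 0.06, and HMX3 by 1.35 ± 0.26, 3.17 ± 0.40 and 0.52 ± 0.07. The other 3, MPZL1, TBC1D16 and WIPI1, were chosen after their values were seen. DPYSL3 fell by 1.71, 2.86 and 1.95 on the log2 scale. Of the 9 higher genes, AIM1, GCNT1 and WIPI1 were also called higher with sh5 in RS411. None of the 9 was among the 4 genes called with sh5 in RCH, and DPYSL3 was called with sh5 in neither of these lines. Pairwise, RS411 and SEM shared 94 higher and 77 lower genes, where independent lists would share 18.7 and 14, RCH and SEM 57 and 11 against 18.2 and 3.37, and RS411 and RCH 19 and 1 against 1.34 and 0.152. These pairs share no library, but they share the hairpin sh2, so an effect of that hairpin other than on NSD2 cannot be told apart.

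**Figure D3:**
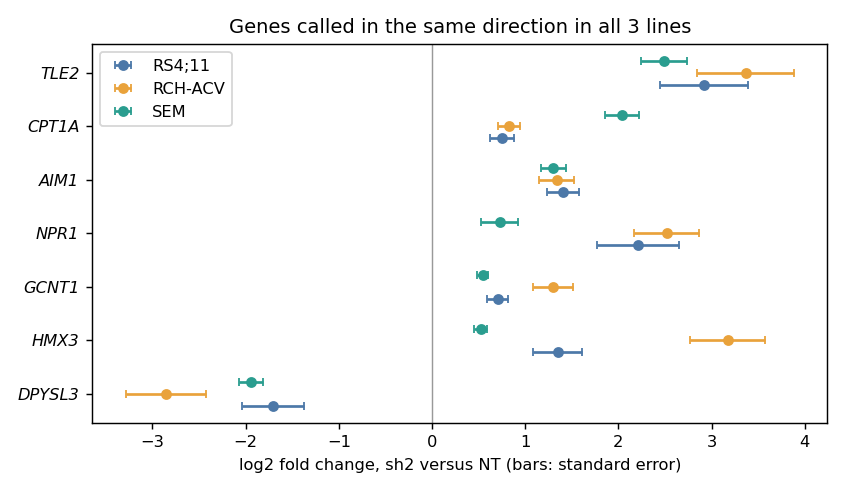
Log2 fold change with sh2 versus NT in RS411, RCH and SEM, with standard errors, of 7 genes called in the same direction in all 3 lines. TLE2 lies between 2.49 and 3.37 and AIM1 between 1.30 and 1.41, while CPT1A reaches 2.04 in SEM against 0.75 in RS411 and 0.83 in RCH.

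In a joint fit of the NT and sh2 libraries of the 3 lines, 2912 of 19573 genes had a called mean response, 1476 higher and 1436 lower, of which 681 calls were at least 2-fold. The response differed between lines for 1639 genes by the interaction test. The joint fit took 1 spread per gene for all 3 lines. The biological coefficient of variation was 0.127 in RS411, 0.232 in RCH and 0.090 in SEM. The interaction p-values may therefore be too small where the difference rests on RCH. Of genes named above, CCSER1 (adjusted p = 8.05e-06), CABLES1 (adjusted p = 1.54e-05), RNF144B (adjusted p = 2.01e-05) and CSF1R (adjusted p = 3.47e-05) were among them. MS4A1 (adjusted p = 0.00489) was raised in RCH and lowered in SEM. The change of NSD2 itself was not shown to differ (adjusted p = 0.703). Without RCH NT replicate 1 the interaction count was 3865, without RCH NT replicate 2 1085, without RCH NT replicate 3 1072 and without SEM sh2 replicate 1 1064, and it was 3172 without a low-count filter and 3223 with the replicate block.

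Genes raised by EK in the overexpression lines were often lower with sh2, in SEM above all. Of the 54 genes called higher with EK in Reh or 697, 33 were called lower with sh2 in at least 1 line and 3 in at least 2 lines. Of the 22 genes raised in 697 and tested in SEM 20 were lower with sh2, where independent lists would share 2.98, and of the 18 raised in Reh 14, where they would share 2.48. NSD2 itself, opposite by design, is among the 33, the 20 and the 14. Without it 19 of 21 genes from 697 and 13 of 17 from Reh were lower in SEM. The 3 genes lower in at least 2 lines were ODF2L (raised by 3.91 ± 0.46 in 697, -0.66 ± 0.10 in RS411, -0.75 ± 0.09 in SEM) and C14orf37 (raised by 2.48 ± 0.28 in 697, -1.36 ± 0.24 in RS411, -3.10 ± 0.13 in SEM), together with NELL1. In the other overexpression line the main fits called none of the 3 with EK. ODF2L had -0.41 ± 0.14 and C14orf37 -0.02 ± 0.20 in Reh, and NELL1 had -0.636 ± 0.425 in 697. The rise of ODF2L in 697 was from 0.632 ± 0.55 to 23.1 ± 7.05 normalized counts. NELL1 was raised by 1.64 ± 0.20 in Reh and had -0.72 ± 0.12 in RS411 and -2.69 ± 0.13 in SEM. Its Reh call was lost with upper-quartile scaling, the stricter filter, the 2 arms alone and each left-out library. The 697 calls of the other 2 were lost with the 2 arms alone, and all 3 RS411 calls without NT or sh2 replicates 1 or 2. Against RS411 the overlaps were 1 gene from Reh (NELL1, against 0.0909) and 2 from 697 (ODF2L and C14orf37, against 0.113). With RCH edgeR called 0 genes lower among the 19 raised in Reh and the 22 raised in 697, where independent lists would share 0.0247 and 0.0328, and LIG4 was higher in both Reh EK and RCH sh2. ROBO1, raised in Reh, was also higher in SEM sh2 (0.17 ± 0.06, adjusted p = 0.0466). Across all genes tested in both, the changes with EK and with sh2 correlated at 0.018, -0.141 and -0.017 for Reh and -0.129, 0.005 and -0.155 for 697 (RS411, RCH and SEM in that order). These comparisons share no library.

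**Figure D4:**
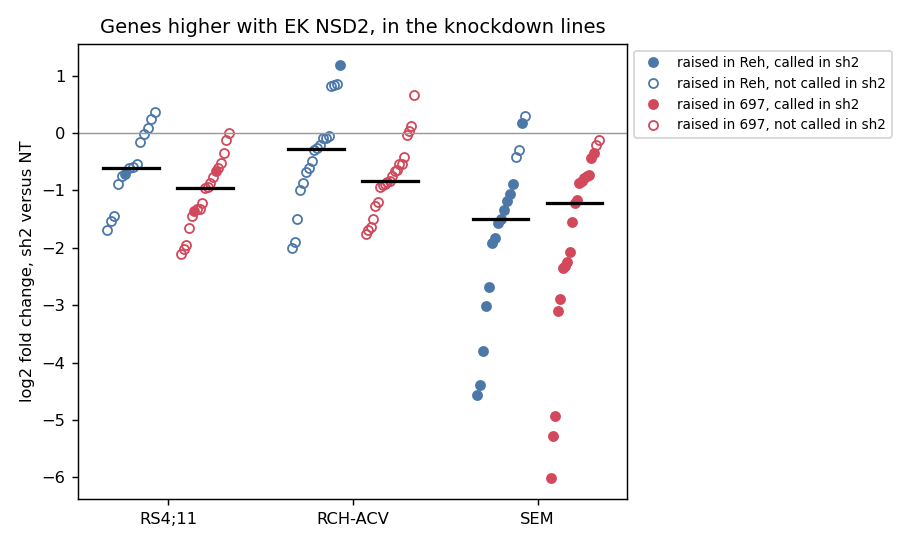
Log2 fold change with sh2 versus NT, in each knockdown line, of the genes called higher with EK versus EV in Reh or 697 other than NSD2, with filled points for genes called in sh2 and lines at the medians. In SEM the medians are -1.49 for the genes raised in Reh and -1.21 for those raised in 697.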

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

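The tests on the size of the NSD2 reduction, on spread against RS411 alone, on gene sets of equal size and on the level of myeloid genes were chosen after the result was seen. The response to sh2 differed between RS411, RCH and SEM for 1639 genes by the interaction test, which took 1 spread per gene for all 3 lines. This difference singles out the genes here. Among those named for the size of their sh2 change, for calls in all 3 lines or for opposite calls in EK and sh2, the adjusted interaction p was 8.05e-06 for CCSER1, 1.54e-05 for CABLES1, 4.41e-05 for FOXP2, 0.000109 for NES, 0.000159 for SPRY4, 0.000162 for HMX2, 0.000168 for MMP16, 0.000208 for MPDZ and 0.00023 for HMX3. It was 0.000249 for CNN2 and ZBTB46, 0.000492 for CPT1A, 0.00127 for MICAL2, 0.00135 for RFX8, 0.00143 for AKR1C3, 0.00145 for ANGPT1, 0.00149 for CDC42EP1, 0.00255 for FREM2, 0.00489 for MS4A1 and 0.00556 for NACC2. For NELL1 it was 0.00682, for NELL2 0.00996, for RNF150 0.0216, for NAPSB 0.0238, for GCNT1 0.0316, for DUSP6 0.0319 and for SESN3 0.0462. In 60 relabellings of NT and sh2 within the lines only the real one, 1 of 60, gave 1639 genes, the highest other giving 1159, and 1 of 60 gave the 2912 genes of the mean response, the highest other giving 273. Relabelling within the lines removes the whole sh2 response. It therefore cannot tell a response that differs between lines from one that is alike in all of them.

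Other splits of 6 libraries number 10, too few for a share under 0.05. The real split gave 28 genes in 697 EK versus EV, 31 in WT versus EV, 286 and 82 in RS411 sh2 and sh5, 239 in RCH sh2, and 4760 and 3623 in SEM sh2 and sh5, the highest other being 0 each time, so that 1 of 10 was as large. For RCH sh5 the real split gave 4 and the highest other 2 (1 of 10), and for 697 EK versus WT all 10 gave 0.

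More genes were called with sh2 in SEM (4760) than in RS411 (286) or RCH (239). Depth is argued against, since SEM reads thinned to the total of the shallowest knockdown library still gave 4291 calls. Against RS411, lower spread between SEM replicates alone is argued against, as the variance of true changes in SEM was 2.92 times as large and at least 1.36 times with libraries left out. Against RCH, lower spread may account for it and cannot be told apart from a larger response, as that variance in SEM was 1.06 times the larger of the other lines, from 0.62 to 1.68 with a library left out. Without sh2 replicate 3, with NSD2 at 50.9%, 50.8% and 49.4% of NT, RCH gave 620 calls, RS411 1560 and SEM 3915. A larger mean NSD2 reduction alone is argued against for RCH and stays open for RS411. The RCH mean joins libraries at 41.6% and 60.2% of NT, while SEM sh2 libraries lay from 48.4% to 52.2%. An effect of this uneven reduction in RCH was not tested. The cell line itself stays open as a biological explanation for both.

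More genes were called without sh2 replicate 3 in RS411 (1560) and RCH (620). Over the 1550 and 600 of these genes that were tested with all libraries, its change had a slope of 0.36 on that of the other sh2 libraries in RS411 and 0.54 in RCH, values that are consistent with a weaker response in that library, where NSD2 stood at 82.5% and 73.8% of NT. The larger number of genes is argued against as the reason, since over as many genes the lower slope of the other libraries was 0.96 in RS411 and 0.90 in RCH. A shift of all libraries numbered 3 is argued against, since the slopes against the NT library of the same number were 0.35 and 0.56. Why the response was weaker was not tested.

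Class II genes lay higher in RCH with sh2. Replicate 1 alone is argued against, as the list without it had adjusted p = 8.59e-10 by camera with the preset correlation. With an estimated correlation the list was not called even with all libraries. RNA of myeloid cells is argued against, since of 5 abundant myeloid genes (LYZ, S100A8, S100A9, TYROBP and FCER1G) none exceeded 0.11 CPM in any sh2 library, while HLA-DQA1 rose from 42.6 to 112.6 CPM. No biological explanation was tested. With sh5 camera with the preset correlation called the class II list higher in RCH, RS411 and SEM, and with an estimated correlation in none of them. In RCH no member was called with sh5, and the list call was lost without sh5 replicate 1 (camera adjusted p = 0.0562). With the preset correlation the rise was therefore not confined to sh2. NSD2 in RCH stood at 57.3% of NT with sh5 and 58.5% with sh2. How far the size of the rise with sh2 in RCH rests on an effect of that hairpin other than on NSD2 cannot be told apart.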

How the results depend on the processing

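The edgeR fit of recovered reads with the replicate block and the left-out libraries for list tests were chosen after the result was seen. Main counts are given in the report, and the cause was not tested for any change below except where fewer genes, arms or libraries, or an added fold threshold, make it. With DESeq2 the counts were 210 in Reh EK versus EV, 139 in WT versus EV and 2 in EK versus WT, 929 and 314 in RS411 sh2 and sh5, and 1077 and 91 in RCH sh2 and sh5. With no low-count filter they were 329, 237 and 18 in Reh, 1281 and 578 in RS411, 1937 and 199 in RCH and 3172 for the interaction. With the stricter filter they were 17 and 18 in 697 EK and WT versus EV, 186 and 48 in RS411 and 0 in RCH sh5. The 2 arms alone gave 7 and 8 in Reh, 9 in 697 EK versus EV, and 66 and 197 in RS411. Upper-quartile factors gave 1 in RCH sh5 and limma on the authors' normalized values 156 in RCH sh2.

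The replicate block gave 1027, 629 and 71 in Reh, where 2 pairs (correlations 0.56 to 0.60) only hint at pairing, 161 and 176 in 697, 2495 and 929 in RS411, 1623 and 46 in RCH, 5591 in SEM sh5 and 3223 for the interaction, and edgeR on recovered reads with the block gave 189 and 205 in 697. Of the results for named genes, counted per comparison, 189 stayed called or not called with it, 4 became called, NSD2 in RCH sh2 among them, and 1 was no longer called. List calls went from 63 to 93, the gains outside the report being 6, 2 and 4 lists in the 3 Reh comparisons and adhesion receptors, higher, in RCH sh2 (0.0275). In RCH sh2 the numbers did not pair the libraries.

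At 2-fold or more the counts were 142 and 43 in RS411, 1310 and 890 in SEM and 681 for the mean response. Shared genes at 2-fold or more were 17 higher and 0 lower between RS411 sh2 and sh5, 168 and 482 between SEM sh2 and sh5, 22 and 30 between RS411 and SEM, and 14 and 5 between RCH and SEM. Of genes raised by EK, 0 from Reh and 1 from 697 were lower in RS411, 11 from 697 were lower in SEM, and 0 from Reh were higher in SEM. Of the 63 list calls 0 were left with an estimated correlation between genes. The interaction was not run at 2-fold or more.

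With each library left out in turn, where a lone Reh library is assumed to vary like the other arms, counts ran from 0 to 4 in Reh EK versus EV, 0 to 8 in WT versus EV and 0 to 0 in EK versus WT, 18 to 24, 18 to 29 and 0 to 1 in 697, 11 to 1560 and 5 to 76 in RS411, 15 to 620 and 0 to 2 in RCH, 3915 to 4832 and 2648 to 3899 in SEM, 1064 to 3865 for the interaction and 2239 to 3967 for the mean response. Reversed log2 changes were C14orf37 in Reh EK versus EV (0.07 without EV replicate 2, 0.14 without EK replicate 1; range -0.22 to 0.14), NSD2 in Reh EK versus WT (0.01 without the low-count filter, 0.04 without WT replicate 1, 0.11 without EK replicate 2; -0.14 to 0.11) and in 697 EK versus WT (0.01 without EK replicate 3, 0.01 without WT replicate 1; -0.25 to 0.01), and NELL1 in RCH sh2 (0.43 without NT replicate 1; -0.51 to 0.43). Reversed lists were MYC and ribosome biogenesis in Reh EK versus WT (adjusted p 8.03e-05 to 0.739, the highest without EK replicate 1), mitochondrial transcripts in 697 EK versus EV (0.000293 to 0.827) and EK versus WT (4.49e-07 to 0.577), both without EK replicate 2, and histones in 697 WT versus EV (3.9e-07 to 0.815, without EV replicate 1) and RCH sh5 (4.03e-06 to 0.593, without NT replicate 1). Of the list calls tested in this way 281 stayed, 86 were weaker and 5 reversed, and of results for named genes 747 stayed, 355 were weaker, 3 stronger and 7 reversed. In simulations, given by line above, 54% (Reh) to 96% (SEM) of 2-fold changes were recovered and 7 to 17 unchanged genes called.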

Other observations

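The tests of whether responding genes are long were chosen after the result was seen. The 53 genes other than NSD2 that EK raised in Reh or 697 lay lower with sh2 as a set. Their median log2 fold change was -0.76 in RS411 (33 tested, 30 below 0), -0.65 in RCH (39 tested, 32 below 0) and -1.42 in SEM (38 tested, 36 below 0), and none of 10000 random lists matched on expression lay as low. With an estimated correlation between genes, camera gave p = 0.089, 0.179 and 0.000574 in the same order. For this set, chosen for its rise with EK, the values are consistent with the hypothesis that more or less NSD2 moves the same genes in opposite directions, but across all genes EK and sh2 changes correlated only between -0.155 and 0.018. In SEM length alone is argued against, as the lowest 5% of random lists matched also on classes of genomic span began at -0.47, and 0 of 10000 lay as low. In RS411 and RCH they began at -0.25 and -0.26, and 0 of 10000 lay as low, but length stays open there. Random lists leave out the correlation between genes, and with that correlation estimated the set itself did not pass in these 2 lines.

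Of 13 sets of responding genes 11 were longer than lists matched on expression, the exceptions being those raised in SEM by sh2 and by sh5. The median span was 222 kb for genes raised by EK in Reh (random lists 20.4 kb) and 106 kb in 697 (15.5 kb). Genes lowered by sh2 spanned 53.8 kb in RS411 (20.6 kb), 43.4 kb in RCH (23.2 kb, adjusted p = 0.0334) and 66.5 kb in SEM (18.9 kb). Genes raised by sh2 spanned 30.3 kb in RS411 (23.4 kb, adjusted p = 0.0382), 32.2 kb in RCH (21.5 kb, adjusted p = 0.0026) and 24.7 kb in SEM (30.1 kb, adjusted p = 0.0013 for shorter), and those raised by sh5 in SEM 27 kb (29.3 kb, adjusted p = 0.0559 for shorter). Spans are those of GRCh38, while the reads were aligned to hg19.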
